A study of Mus musculus with 8 samples.

How the data were processed

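Single CD8 T cells sorted from spleen and liver were profiled with 10x Genomics 5′ chemistry, giving an expression library and a TCR library for each of 2 genotypes (WT C57BL/6 and homozygous EomesTG) and 2 tissues. According to the submitters' notes, cells of 3 mice of each strain were pooled before sorting, so each genotype and tissue is 1 library, and spleen and liver of a genotype share a pool and are not replicates. The submitters' processing notes name Cell Ranger and the mm10 genome, and the matrix headers carry software version 3.1.0 and format version 2. Expression values are deposited as raw UMI counts per gene and cell barcode, without normalization. The contig tables are deposited as counts of UMIs and reads per assembled receptor contig, and all of their contigs were marked as high-confidence contigs of cells. The deposited barcodes had already been filtered by the authors, with lowest totals of 500, 507, 500 and 508 UMIs in WT spleen, EomesTG spleen, WT liver and EomesTG liver, the order used in the lists that follow. The matrices held 31053 genes. The sequence of the transgene is not given in the sources used here, so its reads were not separated from those of the endogenous gene. Gene positions come from the GENCODE M21 annotation of GRCm38.

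The deposited barcodes numbered 5415, 5774, 3327 and 4587. Barcodes with at least 500 UMIs, at least 300 genes and under 10% mitochondrial UMIs were kept, which left out 80, 48, 177 and 66. Scrublet, as implemented in scanpy, was run on the 5335, 5726, 3150 and 4521 barcodes kept and marked 1, 0, 0 and 3, which were left out; this is under 0.5% and so few that it has not worked on these data, and 0 barcodes had more than 2 productive chains of a locus. Barcodes with 2 productive TRB chains made up 6.34, 6.16, 6.81 and 3.90% and were kept, with an alternative that leaves them out. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen without Eomes, antigen receptor segments, mitochondrial, ribosomal protein and sex-linked genes, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0, without integration. This gave 19 clusters. They were named by judgement from marker lists, mostly by listed markers higher than in the other clusters, even where, as in clusters 5, 8 and 18, none was among the 10 leading genes; 6 clusters that fitted no list well kept their number, although 5 of them had 1 marker of a list among those genes. A cluster of 29 cells led by genes of other cell types (Jchain, H2-Aa, Lyz2) was left out, and 5332, 5726, 3127 and 4514 T cells were analysed. They had medians of 1628, 1571, 1743 and 1552 genes per cell. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.

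EomesTG was compared with WT in each tissue, and liver with spleen in each genotype. UMIs were summed over the analysed T cells and divided by their total, and the ratio of these CPM was given with an exact conditional binomial interval. Genes needed at least 50 UMIs over both sides. Against a side with 0 UMIs the fold was computed at 3 counts over the library and given as a lower bound. For a share of 0 the limit given is 3 counts of the total, which lies below the upper bound of the exact interval. With 1 library per group no p-value, standard error or count of differing genes over the genome was computed. Genes were named by a rule set before the data were examined: the 10 highest and the 10 lowest by the interval bound nearest to equality, at 1.5-fold or more, without antigen receptor, mitochondrial and ribosomal protein genes, models named Gm plus a number or ending in Rik, sex-linked genes and the listed markers of cells other than T cells, and Eomes, Pdcd1 and Cxcr6 in every comparison. Within classes and between expanded and single-cell clones the rule named 5 each way. Some of the genes that the rules select are not reported here. The 20 gene lists, the comparisons, the filters and 23 of the 28 alternatives were likewise chosen before the data were examined. For each list the members at least 1.5-fold higher or lower with an interval on that side of equality were counted, and the median log2 ratio was placed among the medians of 10000 random lists matched on size and expression (a percentile of 0 or 100 is below or above all of them). Such percentiles treat genes as independent, which they are not. Up to 4 counted members could be named. The lists were naive, memory, cytotoxic effector, tissue residency, egress and recirculation, inhibitory receptors and exhaustion, NK receptors and adaptors, chemokines and cytokines, chemokine receptors and integrins, cytokine receptors, transcription factors, cell cycle, interferon response, immediate early, heat shock, TCR signalling and feedback, glycolysis, mitochondrial oxidation, apoptosis and survival, and MHC class I genes. The listed symbol Cd244a is not among the gene names of the matrices, which carry Cd244. The list of inhibitory receptors and exhaustion also holds genes that are not inhibitory receptors, such as Tox, Nfatc1, Nr4a2 and Entpd1. Where counts or medians of inhibitory receptor genes are given, that whole list is meant. Which lists were followed as leading results under the alternatives was chosen after a first run, with their values seen: cytotoxic effector and cell cycle (spleen), inhibitory receptors and naive (liver), immediate early and residency (WT tissue), residency and inhibitory receptors (EomesTG tissue).

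Shares of cells with a UMI of a gene were taken after thinning each cell to 2000 UMIs, without shallower cells. The planned background was a cluster of other cell types of at least 30 cells; it held 29, so naive-like cells served in its place. A clone was defined by the V gene, nucleotide junction and J gene of the productive TRB and TRA chains with the most UMIs, and 3980, 4157, 2381 and 3252 T cells had both chains (74.6, 72.6, 76.1 and 72.0%). Expansion was measured per library and as the mean of 1000 draws of as many cells as the smallest library held. Expanded clones held at least 3 cells, and expression was compared between expanded and single-cell clones where both sides had at least 100 cells. V gene use counted each clone once, and the 3 genes differing most each way were named. The grouping of TRAV and TRAJ genes by position was added after V gene use was seen.

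The ratio step was tested on simulated data, Poisson counts drawn around the pooled mean of the libraries compared, over 10771, 10801, 10766 and 10925 genes in the spleen genotype, liver genotype, WT tissue and EomesTG tissue comparisons. Of genes given a 2-fold difference, 100, 99.0, 97.0 and 98.0% were recovered, and of genes given a 4-fold difference 100%. Of unchanged genes, 0.416, 0.368, 0.492 and 0.457% passed 1.5-fold, and intervals covered the true ratio for 95.3, 95.7, 95.4 and 95.7% of genes. Thinning of a simulated repertoire differed from its exact value by 0.16% over 1000 draws. The simulated noise is the counting error that the intervals assume, so these checks cover that error and not differences between mice. Alternatives changed the cell filter, doublets, scaling, the weight of cells and clones, the gene minimum, the clustering, the definition of a clone, thinning and the size of an expanded clone, and 5 more were added after the data were seen. Velocity, trajectory and receptor specificity were not analysed here.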

Results

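CD8 T cells were sorted from the spleen and the liver of wild-type (WT) C57BL/6 mice and of mice homozygous for an Eomes transgene (EomesTG), in which T cells express extra Eomes. The question of the series was how a gain of Eomes, a T-box transcription factor of memory and cytotoxic lymphocytes, shapes the transcriptional program and the clonal expansion of CD8 T cells in the 2 organs. Cells of 3 mice of a strain were pooled before sorting, and each genotype and tissue gave 1 droplet library of RNA and 1 library of T cell receptors (TCR), 8 libraries in all. After filtering, 5332 T cells of WT spleen, 5726 of EomesTG spleen, 3127 of WT liver and 4514 of EomesTG liver were analysed. They held 28749912, 28282240, 18940149 and 20500247 unique molecular identifiers (UMIs), with medians of 5024, 4751.5, 5461 and 3917.5 UMIs per cell. With 1 library per group no difference could be tested against the spread between mice, and spleen and liver of a genotype came from the same pool. Levels are CPM (UMIs summed over cells, per 1e+06 UMIs of the library), ratios are log2, and all 95% intervals (exact Poisson for levels, exact binomial for ratios and shares) cover counting error only. Each value comes from 1 library and has no replicate check.

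Eomes RNA was higher in EomesTG than in WT T cells in both organs, and 2 genes that mark liver-homing and chronically stimulated T cells behaved differently between the organs. Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, forward strand, all positions on GRCm38) was 1.54-fold higher in EomesTG spleen and 2.15-fold higher in EomesTG liver. Its level was 87.0 (83.6 to 90.4) CPM in WT spleen, 134 (130.0 to 139) in EomesTG spleen, 84.7 (80.6 to 89.0) in WT liver and 182 (176 to 188) in EomesTG liver, with log2 ratios of 0.63 (95% interval 0.55 to 0.70) in spleen and 1.10 (1.02 to 1.19) in liver. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, reverse strand), which encodes the inhibitory receptor PD-1, was 19.8-fold higher in EomesTG than in WT liver, at 460.4 (451 to 469.8) against 23.2 (21.1 to 25.5) CPM. In spleen it was low in both genotypes, at 10.6 (9.47 to 11.9) against 6.89 (5.96 to 7.92) CPM. Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760, forward strand), the chemokine receptor that holds lymphocytes in the liver, was 5.37-fold lower in EomesTG than in WT spleen, at 9.44 (8.34 to 10.6) against 50.7 (48.1 to 53.3) CPM. In liver it was 2.46-fold higher, at 357 (348 to 365) against 145 (139.7 to 151) CPM, but its log2 ratio was −0.29 without clusters 2, 10 and 12, which came mostly from EomesTG liver and were left out as an alternative chosen after they were seen. Reads of the transgene and of the endogenous Eomes gene were not told apart. Cxcr6 lies within the span of Fyco1, a gene of the opposite strand, whose log2 ratio was −0.16 (−0.30 to −0.009) in spleen, at 25.3 against 28.2 CPM, and 0.27 (0.08 to 0.46) in liver, at 26.6 against 22.1 CPM.

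**Figure D1:**
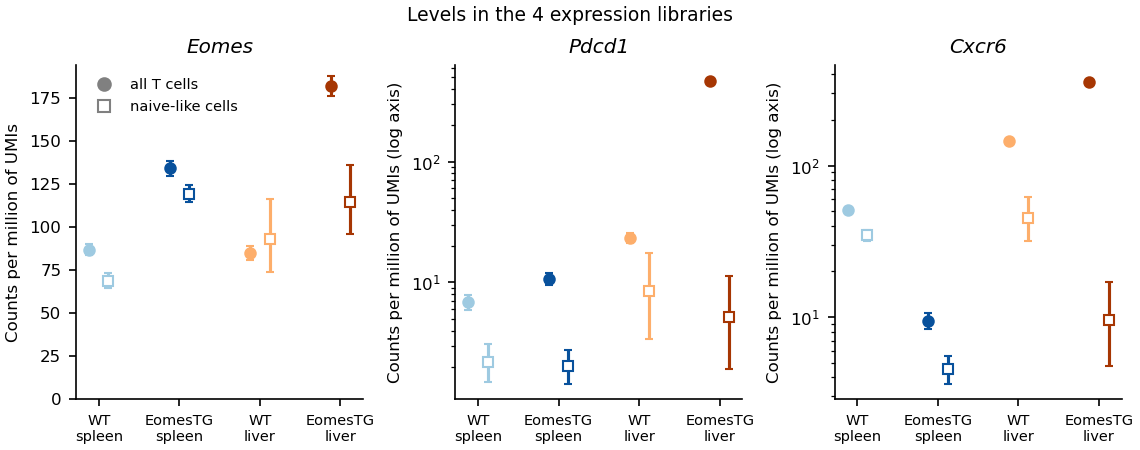
Levels of Eomes (linear axis), Pdcd1 and Cxcr6 (log axes) in CPM in the 4 expression libraries, for all T cells (filled circles) and naive-like cells (open squares), with exact Poisson 95% intervals. Pdcd1 reached 460.4 CPM over all T cells of EomesTG liver and 5.21 CPM in its naive-like cells, while Cxcr6 was lower in EomesTG than in WT naive-like cells of both organs.

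In spleen, EomesTG T cells had less RNA of cytotoxic effector and cell cycle genes than WT T cells and more RNA of heat shock and immediate early genes. Klrg1, a receptor of terminal effector cells, had a log2 ratio of −1.62 (95% interval −2.08 to −1.18), the granzyme gene Gzma −1.60 (−1.72 to −1.47), and the egress receptor gene S1pr5 −1.47 (−1.87 to −1.08). The proliferation genes Mki67 and Top2a had ratios of −1.31 and −1.31. These ratios sum over all T cells of a library and do not tell fewer such cells from less RNA per cell. Cycling-like cells took 2.42% of WT and 0.943% of EomesTG spleen T cells, and effector-like cells 2.10% and 0.664%. The inducible heat shock protein genes Hspa1a (204 against 2.85 CPM) and Hspa1b (112 against 3.27 CPM) were 71.4-fold and 34.3-fold higher. With 1 library per group, handling of the suspensions cannot be told apart from genotype for heat shock and immediate early genes. Spdya, which encodes an activator of cyclin-dependent kinases, was at 11.1 CPM in EomesTG spleen and had 0 UMIs in WT spleen, so that it was at least 106-fold higher.

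By the fixed rule of size, the other genes with the most certain higher level in EomesTG spleen were Nr3c2, the mineralocorticoid receptor (5.19, 3.61 to 7.49), the ephrin receptor gene Epha3 (4.50, 3.23 to 6.15), Crhbp (4.02, 2.93 to 5.37), the small heat shock protein gene Hspb1 (4.31, 2.90 to 6.22), the gene model AC168977.2 (4.27, 2.65 to 6.59), the surface antigen gene Ly6c1 (2.84, 2.36 to 3.36) and the interferon-inducible GTPase gene Iigp1 (2.43, 2.18 to 2.69). Of these, Nr3c2 and AC168977.2 rest on 3 UMIs each in WT spleen. The genes with the most certain lower level were the cyclophilin gene Ppic (−3.04, −3.38 to −2.72), Auts2 (−3.63, −4.73 to −2.71), the scavenger receptor gene Cd163l1 (−3.06, −3.71 to −2.47), Cd40lg, the ligand of CD40 (−3.10, −4.05 to −2.26), the chemokine receptor gene Ccr10 (−3.70, −5.63 to −2.26), the channel gene Trpm1 (−2.71, −3.21 to −2.24), Dapl1, a gene of naive T cells (−2.32, −2.41 to −2.24, 47.1 against 235 CPM), Cxcr6 (−2.42, −2.62 to −2.24), Fam71b (−2.71, −3.42 to −2.05) and the homing receptor gene Gpr15 (−2.59, −3.21 to −2.01).

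Of the gene lists fixed beforehand, 8 of the 12 measured cytotoxic effector genes were at least 1.5-fold lower in EomesTG spleen and 0 higher, with a median log2 ratio of −1.04, below the medians of all 10000 random lists matched on expression. Of the cell cycle genes, 12 of 14 were lower (median −1.16, percentile 0), with Pclaf −1.55 and Ccna2 −1.25. In the list of NK receptors and adaptors, 9 of 15 were lower and 2 higher (median −1.13, percentile 0), with Fcer1g −2.63 and Klrk1 −1.81 against Klra8 2.504 and Klra9 1.86. Cluster 16, led by genes such as Klra1, Gpr15, Klra7 and Fcer1g, held 5.12% (4.54 to 5.75) of WT and 1.01% (0.770 to 1.31) of EomesTG spleen T cells. It fitted no marker list well, so these shares are given per library without a comparison. Tissue residency genes were lower in 5 of 11 (median −0.69, percentile 0), led by Zfp683 −2.56, Chn2 −2.36 and Itgae −2.27. Among transcription factors, 5 of 19 were lower (median −0.27, percentile 0.01), with Rora −1.21, Zeb2 −0.94 and Tbx21 −0.80. Immediate early genes, which tissue dissociation induces, were higher in 6 of 13 (median 0.58, percentile 100), with Fosb 1.91, Fos 1.79, Jun 1.23 and Nr4a1 1.10, and heat shock genes in 4 of 10 (median 0.26, percentile 100), with Dnajb1 1.32 and Hsph1 0.90. Inhibitory receptor and exhaustion genes were mixed, with 4 of 12 higher and 1 lower (median 0.009, percentile 56.9). Among them were Lag3 1.20, Nr4a2 0.69, Tigit 0.68 and Cd160 −1.19. Chemokines and cytokines had 2 higher and 2 lower of 11 (median 0.08, percentile 89.9), with Ccl3 1.497, Ccl4 1.43, Il2 −0.91 and Ccl5 −0.64. Of 16 chemokine receptors and integrins, 4 were lower and 1 higher (median −0.10, percentile 3.11), with Cx3cr1 −1.13, Ccr2 −0.94 and Itgax −0.87.

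Of the 12 naive genes only Dapl1 passed 1.5-fold (median 0.14, percentile 99.8), and of the 12 memory genes only Ccl5, which was lower (median −0.13, percentile 0.590). Interferon response genes had 1 higher and 2 lower of 14 (median −0.12, percentile 1.31), with Ifit3b −0.80 and Ifi27l2a −0.70. In TCR signalling, 2 of 16 were higher (Nr4a1 1.10 and Egr2 1.09; median −0.05, percentile 15.2). Hk2 (−1.91) was the lower member among 13 glycolysis genes (median −0.03, percentile 34.7) and Fasl (−1.16) among 14 apoptosis genes (median −0.13, percentile 0.530). No member passed 1.5-fold in egress and recirculation (10 measured, median −0.04, percentile 34.4), cytokine receptors (17, 0.04, percentile 89.5), mitochondrial oxidation (14, −0.09, percentile 6.53) or MHC class I (10, 0.31, percentile 100).

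Within naive-like spleen cells the same directions held for several of these genes. Eomes was higher in EomesTG (0.80, 95% interval 0.69 to 0.91), at 119.7 (115 to 125) against 68.8 (64.6 to 73.2) CPM, and Cxcr6 was lower (−2.94, −3.28 to −2.61), at 4.51 (3.62 to 5.55) against 34.6 (31.6 to 37.8) CPM. Pdcd1 did not differ beyond counting error (−0.12, −0.83 to 0.60). Besides Spdya, which had 0 UMIs in WT cells and was at least 48.6-fold higher, the highest were Hspa1a (6.68, 6.16 to 7.26), Hspa1b (5.64, 5.14 to 6.18), Nr3c2 (5.81, 3.28 to 11.13, on 1 WT UMI) and the NK receptor gene Klra9 (4.93, 3.03 to 8.002, on 2 WT UMIs), and the lowest were Ppic −3.26, Cd200 −3.27, Trpm1 −3.31 and Auts2 −3.73. Ly6a, which encodes the stem cell antigen Sca-1, was at 236 against 37.0 CPM (log2 ratio 2.67). Genes of antigen-presenting cells were also higher in these cells: Cd74 was at 48.4 against 3.31 CPM, H2-Aa at 3.40 against 0.345 CPM and H2-Ab1 at 2.43 against 0.138 CPM (4.14, 2.21 to 7.23); these 3 genes and Ly6a were singled out after their values were seen. Cluster 0 held 63.9% of the EomesTG and cluster 1 46.6% of the WT naive-like spleen cells, so the cells compared fell mostly into different clusters. In the other spleen T cells, the highest genes were Crhbp (5.54, 3.62 to 8.62), Epha3 (4.57), Hspa1a (5.74), Hspa1b (4.69) and Spdya (at least 63.7-fold higher), and the lowest were Cd40lg −4.02, Ppic −2.82, Auts2 −3.85, Cd163l1 −2.48 and Dapl1 −1.98. There Pdcd1 was higher (1.39, 1.10 to 1.68), Eomes was higher (0.67, 0.57 to 0.78) and Cxcr6 was lower (−1.69, −1.93 to −1.46). Inhibitory receptor and exhaustion genes were higher in 6 of 11 (median 0.66), with Lag3 2.12, Tigit 1.398 and Nr4a2 1.30. Ratios of the other spleen T cells were not taken without clusters 2, 10 and 12. With cells thinned to 2000 UMIs, these clusters held 31 of 5353 EomesTG spleen T cells. They also held 16 of the 78 cells with a Pdcd1 UMI. Cytotoxic effector genes were lower in 4 of 12 with 1 higher (median −0.37). That last median was 0.060 when each clone counted once, and over all spleen T cells the cytotoxic median was then −0.50; the largest WT spleen clone was an effector-like clone of 39 cells.

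In liver, EomesTG T cells had far more RNA of inhibitory receptors and exhaustion genes than WT T cells, more of a subset of effector molecules, and less of naive and recirculation genes. Besides Pdcd1 (4.31, 95% interval 4.17 to 4.45), the inhibitory receptor genes Lag3 (3.27, 3.15 to 3.39), Havcr2 (3.09, 2.72 to 3.48) and Cd200r1 (3.39, 3.16 to 3.63) and the exhaustion-associated transcription factor gene Tox (2.80, 2.70 to 2.89) were higher. The granzyme gene Gzma was at 5324 against 634 CPM and the chemokine gene Ccl5 at 27424 against 9521 CPM. The naive T cell genes Lef1 (−1.29, −1.36 to −1.21), Tcf7 (−1.28, −1.35 to −1.20) and Satb1 (−1.32, −1.41 to −1.23) and the egress receptor gene S1pr1 (−1.50000, −1.61 to −1.39) were lower. Clusters 2, 10 and 12 held 42.4%, 11.8% and 11.96% of EomesTG liver T cells. Without them the ratios were Pdcd1 2.64, Lag3 1.65, Havcr2 2.01, Cd200r1 1.4003, Tox 1.33 and Gzma 1.18, and Ccl5 −0.098, Lef1 −0.18, Tcf7 −0.17, Satb1 −0.22 and S1pr1 −0.44. The egress list median was then −0.18, with 0 of its members lower by 1.5-fold.

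The genes with the most certain higher level in EomesTG liver were the lens membrane protein gene Lim2 (7.62, 6.50 to 9.07), the neuropeptide gene Calcb (8.24, 6.38 to 11.29), Spdya (at least 63.1-fold higher, with 0 UMIs in WT liver), Ccdc80 (7.52, 5.66 to 10.57), the incretin receptor gene Glp1r (6.94, 5.57 to 8.82), the trypsin gene Prss2 (6.16, 5.43 to 7.00), the macrophage growth factor gene Csf1 (6.34, 5.36 to 7.56), the transporter gene Slc16a11 (7.76, 5.27 to 13.07), the adhesion receptor gene Adgrg1 (5.70, 5.16 to 6.30) and Cd200r2 (5.47, 5.13 to 5.84). Calcb and Ccdc80 had 2 UMIs each and Slc16a11 had 1 UMI in WT liver. The most certain lower levels were those of Dapl1 (−3.24, −3.43 to −3.04), Cd163l1 (−3.73, −4.83 to −2.81), the antitrypsin gene Serpina1b (−4.26, −6.58 to −2.63), Tmem176b (−3.15, −3.86 to −2.504), Gpr15 (−3.33, −4.37 to −2.43), the NK receptor gene Klra7 (−2.36, −2.501 to −2.22), the granzyme gene Gzmm (−2.31, −2.52 to −2.11), Tmem176a (−2.73, −3.42 to −2.10), the sodium pump gene Atp1b1 (−2.26, −2.48 to −2.04) and Anxa1 (−2.71, −3.50 to −2.004). Serpina1b is expressed by hepatocytes, and the hepatocyte gene Alb, singled out after its value was seen, was likewise lower, at 0.342 against 6.55 CPM.

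By lists, 12 of the 13 measured inhibitory receptor and exhaustion genes were at least 1.5-fold higher in EomesTG liver and 1 lower, with a median log2 ratio of 2.47, above the medians of all 10000 random lists. Naive genes were lower in 9 of 12 (median −1.16, percentile 0). Egress and recirculation genes were lower in 9 of 10 with 1 higher (median −1.16, percentile 0), with Klf3 −1.31, Itgb7 −1.23 and Ccr7 −1.21. Residency genes were higher in 6 and lower in 3 of 12 (median 0.45, percentile 99.9), with Prdm1 2.42 and Chn2 2.11 against Itgae −1.99. Cytotoxic effector genes were divided, 5 higher and 4 lower of 12 (median 0.12, percentile 56.7), with Gzma 3.07 and Gzmk 2.32 against Gzmm −2.31 and S1pr5 −2.002. Chemokines and cytokines were higher in 7 and lower in 4 of 13 (median 0.73, percentile 100), with Il10 3.97, Ccl3 3.42, Ccl4 2.15 and Ccl5 1.53. NK receptors had 8 higher and 9 lower of 18 (median −0.10, percentile 0.420), with Klrc1 1.93, Klre1 1.82 and Ncr1 −2.17. Memory genes had 5 higher and 4 lower of 12 (median −0.33, percentile 0), with Nkg7 1.41, Ly6c2 −1.70 and Il18r1 −1.31. Transcription factors had 8 each way of 20 (median −0.18, percentile 0.0400), with Nfil3 1.92 and Myb −1.71. With each clone counted once the memory median was 0.055 and the transcription factor median 0.035, and the latter was 0.0052 over genes of at least 200 UMIs. Heat shock genes were higher in 6 of 10 (median 0.94, percentile 100), with Hspa1a 1.83, Hspa1b 1.61 and Hsph1 1.47.

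Interferon response genes were lower in 6 of 14 in EomesTG liver (median −0.47, percentile 0), with Ifit3 −1.41 and Oasl2 −1.31, and immediate early genes in 2 of 14 (median −0.18, percentile 0.130), with Fosb −1.11 and Nfkbia −0.60. Chemokine receptors and integrins had 3 higher and 7 lower of 16 (median −0.42, percentile 0), with Ccr2 −1.44 and Ccr9 −1.42, and cytokine receptors 5 and 7 of 17 (median −0.30, percentile 0), with Il10ra 1.23 and Il12rb2 −1.27. TCR signalling genes were higher in 5 of 16 (median 0.32, percentile 99.7), with Cd3e 1.02 and Cd3g 0.97, and apoptosis and survival genes in 6 of 14 with 1 lower (median 0.27, percentile 98.0), with Bcl2a1d 1.30 and Bcl2 1.14. Glycolysis had 1 higher and 1 lower of 13 (Hk1 0.73 and Hk2 −1.03; median 0.11, percentile 60.7). No member passed 1.5-fold among 14 cell cycle genes (median −0.11, percentile 0.420), 14 mitochondrial oxidation genes (median 0.015, percentile 20.2) or 10 MHC class I genes (median 0.28, percentile 96.8). The median over all genes was itself 0.12 above 0, and the lists are to be read against that shift. A scaling by the median of ratios moves every liver ratio by −0.11, after which the glycolysis median was −0.0033.

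Without clusters 2, 10 and 12, an alternative chosen after the clusters were seen, 9 inhibitory receptor genes were still higher in EomesTG liver, with a median of 0.89. Of the naive genes 1 was lower (median −0.093), and the medians of the residency and cytotoxic lists were −0.14 and −0.18. The log2 ratio was 0.62 for Eomes, −0.098 for Ccl5 and −0.29 for Cxcr6. When each clone counted once, the inhibitory median was 1.24 and the naive median −0.21. Within naive-like liver cells, 203 of EomesTG and 139 of WT, the immediate early gene Egr1 (2.36, 1.78 to 3.002), Ly6a (2.08, 1.58 to 2.61), Hspb1 (2.49, 1.35 to 3.87), Hspa1a (1.42, 1.22 to 1.61) and Wdr43 (1.58, 1.16 to 2.03) led the higher genes, and Rgs16 (−3.43, −4.81 to −2.29), the checkpoint gene Ctla4 (−2.82, −3.69 to −2.04), Dapl1 (−2.23, −2.61 to −1.87), Myb (−2.26, −2.999 to −1.58) and the interferon-induced Ifi27l2a (−1.67, −1.86 to −1.49) the lower ones, against a median of −0.16 over all genes. There Eomes was at 115 (96.0 to 136) against 93.4 (73.7 to 117) CPM, Pdcd1 at 5.21 (1.91 to 11.3) against 8.49 (3.41 to 17.5) CPM and Cxcr6 at 9.56 (4.77 to 17.1) against 44.9 (31.6 to 61.8) CPM. Cluster 0 held 73.4% of the EomesTG and cluster 5 46.8% of the WT naive-like liver cells. In all other liver T cells the highest genes were Lim2 (7.64), Calcb (9.26, 6.78 to 14.57), Ccdc80 (7.54, 5.68 to 10.59), Glp1r (6.95) and Spdya (at least 54.6-fold higher), and the lowest Dapl1 −3.59, Cd163l1 −3.72, Tmem176b −3.12, Gpr15 −3.28 and Atp1b1 −2.49. There Pdcd1 was higher (4.35, 4.21 to 4.49), as were Eomes (1.14, 1.06 to 1.23) and Cxcr6 (1.33, 1.27 to 1.398).

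The genotype ratios of the 3 named genes differed between the organs. The log2 ratio in liver minus that in spleen was 0.48 for Eomes, 3.68 for Pdcd1 and 3.72 for Cxcr6. Bounds from the ends of the intervals were 0.32 to 0.64, 3.28 to 4.09 and 3.47 to 3.98. These differences between organs were not tested, since no replicate gives their spread. Without clusters 2, 10 and 12 they were 0.0036, 2.36 and 2.23, and with each clone counted once 0.028, 1.94 and 2.49.

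Between organs of WT mice, liver T cells had more RNA of immediate early, heat shock, residency, NK receptor, cytotoxic and cell cycle genes than spleen T cells. The residency-associated transcription factor gene Bhlhe40 was at 142 against 4.77 CPM, the signalling regulator gene Rgs1 at 654 against 25.1 CPM and the cytokine gene Ifng at 142 against 5.50 CPM. Cxcr6 (1.52, 95% interval 1.43 to 1.61) and Pdcd1 (1.75, 1.51 to 2.003) were higher in liver, and Eomes did not differ beyond counting error (−0.04, −0.13 to 0.05). The stress genes Hspa1a (531 against 2.85 CPM), Hspa1b (245 against 3.27 CPM), Hspb1 (7.65, 6.28 to 9.53) and Atf3 (7.79, 6.24 to 10.08) were among the most certain higher genes, with the sulfatase gene Sulf2 (8.01, 5.51 to 13.32), Osgin1 (6.41, 4.84 to 8.70), Gcnt2 (5.88, 4.73 to 7.34), Bhlhe40 (4.90, 4.65 to 5.16), Rgs1 (4.71, 4.60 to 4.82) and Ifng (4.69, 4.46 to 4.93). In spleen Sulf2 rests on 1 UMI and Atf3 and Osgin1 on 3 each. The most certain lower genes were Acvrl1 −2.86, Hdac9 −2.32, Rapgef4 −1.68, Kcna2 −1.95, Slc16a5 −1.57, Pou2af1 −1.59, Snhg20 −1.27, Nfam1 −1.96, Eng −1.36 and Hacd1 −2.21.

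All 14 immediate early genes were higher in WT liver (median 2.51, percentile 100), with Nr4a1 4.16, Fos 4.02 and Dusp1 3.97, and 6 of 10 heat shock genes (median 0.87, percentile 100), with Dnajb1 3.32 and Hsph1 2.23. Residency genes were higher in 9 of 11 (median 2.35, percentile 100), with Itga1 4.19 and Zfp683 3.14; without the NK-like cluster 14 this median was 1.64 and without the immediate-early-like cluster 4 it was 2.91. NK receptors were higher in 15 of 18 (median 2.11, percentile 100), with Tyrobp 4.56 and Ncr1 3.81. Cytotoxic effector genes were higher in 9 of 12 (median 1.97, percentile 100), with Gzmb 4.39 and Gzma 3.11. Inhibitory receptor and exhaustion genes were higher in 10 of 13 (median 1.96, percentile 100), with Nr4a2 3.59, Ctla4 2.78 and Tigit 2.73. Cell cycle genes were higher in all 14 (median 1.44, percentile 100), with Cdk1 1.74 and Mki67 1.66. Chemokines and cytokines were higher in 9 of 12 (median 1.70, percentile 100; Ccl3 4.39, Ccl4 4.24 and Csf2 3.73), memory genes in 7 of 12 (median 0.64, percentile 100; Ccl5 1.51 and Id2 1.49) and apoptosis and survival genes in 7 of 14 (median 0.46, percentile 100; Fasl 2.99 and Bcl2a1d 2.10). Transcription factors had 11 higher and 2 lower of 20 (median 0.83, percentile 100; Nfil3 3.02 and Prdm1 2.35), chemokine receptors and integrins 8 and 2 of 16 (median 0.60, percentile 100; Itgax 2.06 and Cx3cr1 1.99), and cytokine receptors 6 and 2 of 17 (median 0.36, percentile 99.9; Il12rb2 2.99 and Il6ra −1.01). Naive genes were lower in 4 of 12 (median −0.55, percentile 0; Dapl1 −1.07). Glycolysis was higher in 3 of 13 (median 0.38, percentile 99.7; Gapdh 0.83 and Tpi1 0.69), interferon response in 1 of 14 (median 0.15, percentile 86.0; Isg15 0.69) and TCR signalling in 1 of 16 (median 0.14, percentile 76.1; Nr4a1). Egress genes were split, 2 higher and 2 lower of 10 (median 0.07, or −0.012 with median-of-ratios scaling, percentile 35.3; Cxcr4 1.60, Klf2 1.52 and Il6ra −1.01). No member passed 1.5-fold among mitochondrial oxidation (14 measured, median 0.06, percentile 31.2) and MHC class I genes (10, 0.25, percentile 94.3).

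Between organs of EomesTG mice, liver T cells had more RNA of residency, inhibitory receptor, NK receptor, cytotoxic effector and cell cycle genes than spleen T cells, and less of naive and egress genes. Gzma was at 5324 against 24.2 CPM, Cd200r2 at 159.5 against 0.0354 CPM and Chn2, a Rac GTPase-activating protein gene of resident cells, at 151 against 0.990 CPM. Pdcd1 (5.43, 95% interval 5.27 to 5.61) and Cxcr6 (5.24, 5.06 to 5.42) were higher in liver, as was Eomes (0.44, 0.38 to 0.51). The other most certain higher genes were Glp1r (9.51, 7.03 to 14.82) and Cd244 (7.54, 6.73 to 8.50), with Cited4 (at least 309-fold), Ccdc80 (at least 183-fold), the growth factor gene Areg (at least 143-fold), Rnf165 (at least 141-fold) and Tmprss6 (at least 112-fold higher), these 5 with 0 UMIs in EomesTG spleen. Cd200r2 and Glp1r rest on 1 UMI each in spleen. The lower genes were Slc16a5 −2.77, Rapgef4 −2.67, Tmem108 −2.51, Pgpep1l −3.59, Ramp1 −2.36, Eng −2.51, Igf1r −3.19, Myb −2.24 and Kbtbd11 −2.13. The median over all genes lay at 0.19, and a median-of-ratios scaling moves every ratio by −0.20.

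Residency genes were higher in EomesTG liver in 9 of 12 (median 4.86, percentile 100), with Bhlhe40 5.93, Itga1 5.54 and Rgs1 5.54. Inhibitory receptor and exhaustion genes were higher in 12 of 13 with 1 lower (median 3.89, percentile 100), with Cd200r1 6.48, Entpd1 5.52 and Nr4a2 5.08. Without clusters 2, 10 and 12 these medians were 3.93 and 3.02, and the ratio of Eomes was −0.040; with each clone counted once the inhibitory median was 2.78. Naive genes were lower in 11 of 12 (median −1.58, percentile 0; Lef1 −1.9999 and Tcf7 −1.97) and egress genes in 7 of 10 with 2 higher (median −1.16, percentile 0; S1pr1 −1.72 and Itga4 1.61). NK receptors were higher in 16 of 18 (median 3.204, percentile 100; Klra5 6.55 and Klre1 5.26), cytotoxic effector genes in 10 with 1 lower of 12 (median 2.14, percentile 100; Gzmb 6.13 and Fasl 5.34) and cell cycle genes in all 14 (median 2.45, percentile 100; Cdk1 3.06 and Ccna2 2.96). Immediate early genes were higher in 10 of 14 (median 1.70, percentile 100; Atf3 5.33 and Dusp1 3.45) and heat shock genes in 9 of 10 (median 1.56, percentile 100; Dnajb1 3.25 and Hspa1a 3.21). Chemokines and cytokines had 10 higher and 2 lower of 13 (median 2.35, percentile 100; Ccl3 6.31 and Ifng 5.91), transcription factors 14 and 5 of 19 (median 1.70, percentile 100; Prdm1 5.46 and Nfil3 5.07), memory genes 5 and 2 of 12 (median 0.50, percentile 96.2; Ccl5 3.68 and Id2 2.77), chemokine receptors 8 and 5 of 16 (median 0.60, percentile 99.6; Ccr9 −2.05) and cytokine receptors 6 and 4 of 17 (median −0.05, percentile 1.36; Il7r −1.69 and Il12rb1 1.64). Apoptosis and survival genes were higher in 8 of 14 (median 1.07, percentile 100; Bcl2a1d 3.92), TCR signalling genes in 7 of 16 (median 0.41, percentile 94.5; Nr4a1 2.59 and Cblb 1.22), glycolysis genes in 6 of 13 (median 0.57, percentile 98.5; Hk2 1.34) and mitochondrial oxidation genes in 3 of 14 (median 0.16, percentile 30.2; Etfb 1.46). The median of the last list was −0.042 with the other scaling. Interferon response had 2 higher and 5 lower of 14 (median −0.20, percentile 0.150; Usp18 −1.60 and Isg20 1.43), and none of the 10 MHC class I genes passed 1.5-fold (median 0.20, percentile 36.8).

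**Figure D2:**
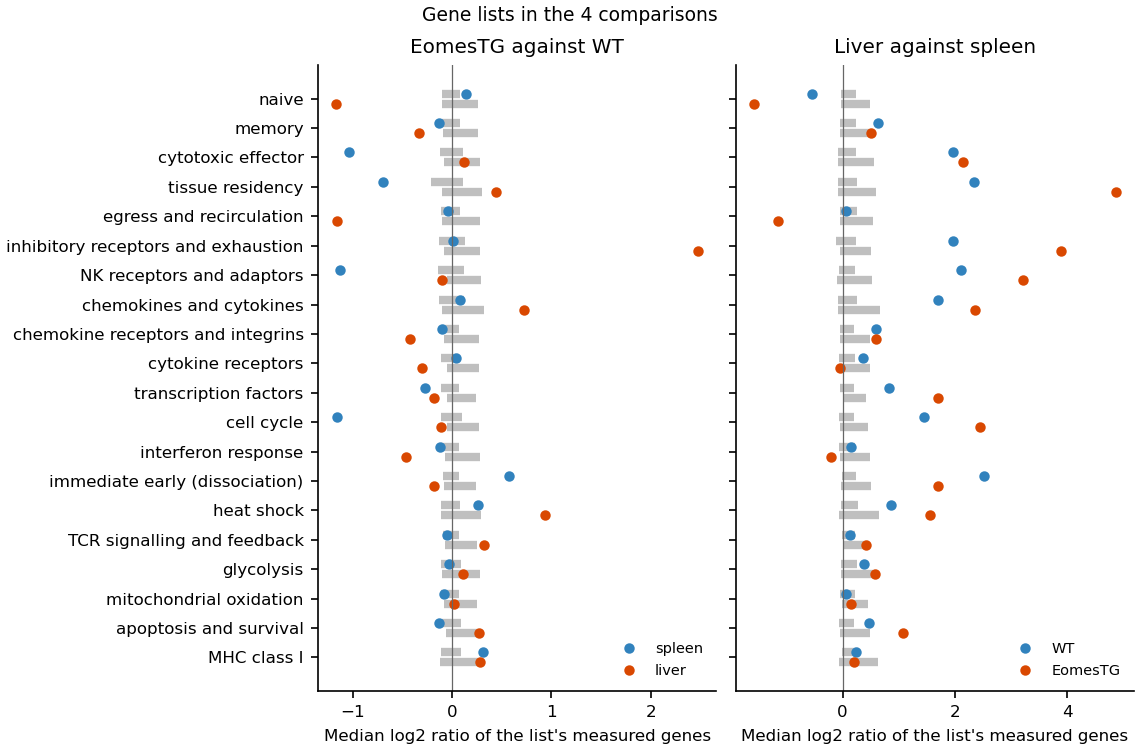
Median log2 ratio of the measured genes of each of 20 fixed lists, for EomesTG against WT (left; spleen blue, liver orange) and for liver against spleen (right; WT blue, EomesTG orange); grey bars span the central 95% of medians of 10000 random lists matched on size and expression. The inhibitory receptor list lies at 0.009 in spleen and 2.47 in liver for EomesTG against WT, and the cell cycle list at −1.16 and −0.11.

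Naive-like cells, led by genes such as Igfbp4, Ccr7 and Il7r, made up a larger share of EomesTG than of WT spleen T cells, 73.3% (72.1 to 74.4) against 55.5% (54.1 to 56.8). In liver they made up 4.50% (3.91 to 5.14) of EomesTG and 4.45% (3.75 to 5.23) of WT T cells. The shares of the other classes are listed per library. Unnamed clusters fitted no marker list well, so their shares are not compared between groups. Immediate-early-like cells took 0.0563%, 0.332%, 38.2% and 11.4% of WT spleen, EomesTG spleen, WT liver and EomesTG liver, in that order. Memory-like cells took 26.4%, 16.3%, 4.54% and 2.35%, effector-like cells 2.10%, 0.664%, 18.2% and 3.74%, and cycling-like cells 2.42%, 0.943%, 7.23% and 4.25%. Interferon-response-like cells took 4.48%, 3.09%, 3.42% and 0.797%, and NK-like cells, which carried Ncr1 and Tyrobp beside TCR chains, 0.0938%, 0.0349%, 11.9% and 1.93%. Clusters 2, 10 and 12, led by genes such as Cd200r2, Prss2 and Slc16a11, stayed unnamed, and their cells came mostly from EomesTG liver. The other unnamed clusters, 13, 15 and 16, took 0.731%, 0.244%, 8.41% and 4.45%, 2.85%, 3.51%, 1.66% and 0.354%, and 5.12%, 1.01%, 0.736% and 0.0886%, in the same order. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type. At a coarser clustering the naive-like shares of EomesTG and WT spleen were 85.8% and 74.9%.

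With each cell thinned to 2000 UMIs, at least 1 Pdcd1 UMI was found in 49.8% of EomesTG liver T cells and 3.61% of WT liver T cells, against 1.46% and 1.16% in spleen. The exact 95% intervals of the liver shares were 48.2 to 51.3 and 2.97 to 4.35. Naive-like cells took the place of the planned background, since the cluster of other cell types held 29 cells and 30 were required. They had 0.181%, 0.335%, 1.60% and 0.526% in the order WT spleen, EomesTG spleen, WT liver and EomesTG liver. In the same order, Tox was found in 7.27%, 8.35%, 9.34% and 48.4% of T cells, Cxcr6 in 8.68%, 1.51%, 20.8% and 45.2%, Eomes in 12.9%, 21.9%, 13.2% and 29.2%, Cd44 in 7.98%, 6.78%, 13.2% and 9.73% and Mki67 in 1.67%, 0.654%, 5.11% and 5.91%. Naive-like cells had 6.28%, 0.825%, 7.20% and 2.11% for Cxcr6, 10.6%, 20.4%, 12% and 17.9% for Eomes, 7.91%, 7.96%, 6.40% and 3.68% for Tox, 5.06%, 5.39%, 6.40% and 4.21% for Cd44 and 0.253%, 0.0773%, 0.800% and 1.05% for Mki67. The intervals of T cells and naive-like cells overlapped for Tox in both spleens and WT liver. They also overlapped for Eomes and Cd44 in EomesTG spleen and WT liver, and for Pdcd1 and Mki67 in WT liver. For Eomes in WT spleen the intervals were 11.97 to 13.8 and 9.46 to 11.8. An overlap does not place a share at background, since naive-like cells are among the T cells they are set against. In EomesTG spleen they were 3881 of the 5353 cells thinned. They also carried Eomes RNA themselves, so they are no background for that gene. Without thinning, Pdcd1 was found in 2.78%, 2.88%, 8.09% and 61.7%, Cxcr6 in 17.7%, 3.25%, 36.7% and 58.3% and Eomes in 26.6%, 40.9%, 27.5% and 46.3% of T cells. Cells below 2000 UMIs, 254, 373, 194 and 586, were left out. The median depths at thinning were 5110.5, 4888, 5640 and 4200 UMIs for T cells, and 4922, 4755, 6017 and 5941 for naive-like cells.

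Clonal expansion, the point of the receptor libraries, was far larger in EomesTG liver than in the other 3 libraries. Cells of clones of at least 3 cells made up 69.2% (67.6 to 70.8) of EomesTG liver T cells with both chains, 15.7% (14.3 to 17.2) in WT liver, 2.06% (1.64 to 2.55) in WT spleen and 1.15% (0.853 to 1.53) in EomesTG spleen. Thinned to 2381 cells each, the shares were 68.0%, 15.7%, 1.58% and 0.899%. Without the largest clone of each library, the thinned shares of WT and EomesTG spleen were 0.559% and 0.639%. EomesTG liver had 1024 clones in 3252 cells, of which 29 held at least 10 cells, and WT liver had 2010 clones in 2381 cells, of which 6 held at least 10. WT spleen had 3876 clones in 3980 cells and EomesTG spleen 4076 in 4157. The largest clone took 15.1% (13.9 to 16.4) of EomesTG liver, 4.79% (3.97 to 5.72) of WT liver, 0.980% (0.698 to 1.34) of WT spleen and 0.241% (0.115 to 0.442) of EomesTG spleen, and the 10 largest took 49.5% (47.8 to 51.3) of EomesTG and 10.2% (9.06 to 11.5) of WT liver. Thinned Gini indices of clone size were 0.0206, 0.0136, 0.154 and 0.654 and inverse Simpson indices 1904, 2273, 305 and 19.6, in the order WT spleen, EomesTG spleen, WT liver and EomesTG liver. Because 3 mice were pooled, a clone could not be traced to a mouse, and the largest clones were not assigned to any of them. Without its 2 largest clones, chosen as an alternative after they were seen, EomesTG liver still had a thinned share of 56.5% and WT liver 9.68%.

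**Figure D3:**
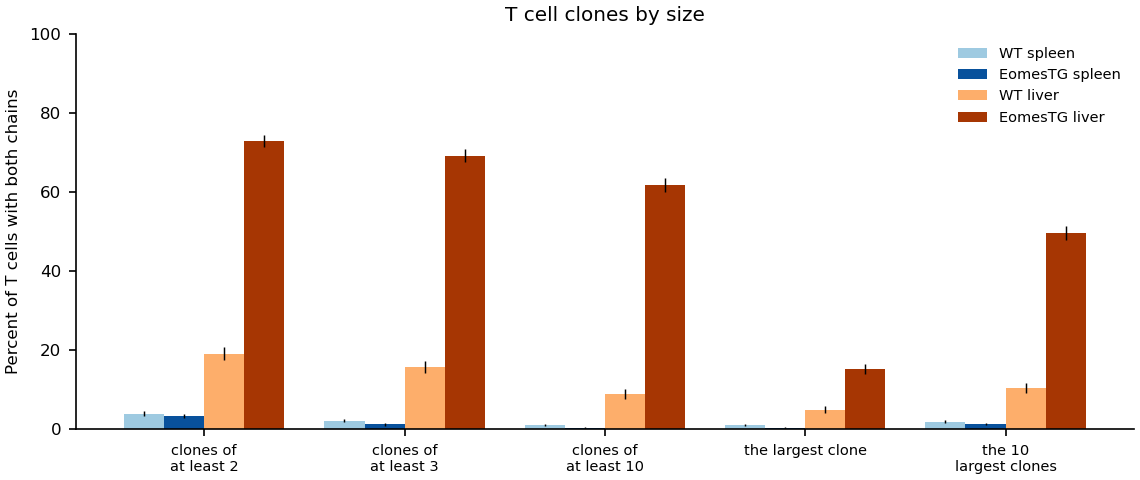
Percent of T cells with both TCR chains that belong to clones of at least 2, 3 and 10 cells, to the largest clone and to the 10 largest clones, per library and without thinning; bars start at 0 and error lines are exact binomial 95% intervals. EomesTG liver stands at 61.7% for clones of at least 10 cells, and WT liver at 8.78%.

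The largest EomesTG liver clone held 492 cells, 344 of them in cluster 2, with TRBV3 and TRAV14D-1 and the TRB junction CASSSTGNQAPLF. The next held 447 cells with TRBV15, TRAV19 and the junction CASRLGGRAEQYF, of which 348 lay in cluster 2. Neither was seen in EomesTG spleen. A clone of 233 cells with TRBV12-1, TRAV13-1 and the junction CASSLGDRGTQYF was found with 8 cells in spleen. The clone of rank 5 (75 cells, TRAV9-4, 6 in spleen) carried the same TRB chain, so that 308 liver cells shared it. Only 1 TRA chain per cell was kept, so these 2 entries may be 1 clone with 2 TRA chains, which was not tested. In the clones of 492, 447 and 233 cells, Pdcd1 was at 765, 827 and 583 CPM and Cxcr6 at 516, 482 and 458 CPM. The largest WT clone, with TRBV29, TRAV10 and the junction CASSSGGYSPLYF, held 114 cells in liver, 58 of them effector-like, and 39 in spleen, 26 of them effector-like. The next WT liver clone held 45 cells, 44 of them NK-like, with TRBV10 and TRAV7-3, and was not seen in spleen. In EomesTG liver, 2035 of 2171 cells of clusters 2, 10 and 12 belonged to clones of at least 3 cells (93.7%), as did 77.5% of 160 cycling-like cells. Of 144 naive-like cells 0 did, which allows a share of up to 2.08%, and of 346 immediate-early-like cells 1 did. In WT liver such cells made up 29.9% of effector-like, 32.9% of NK-like and 39.6% of cycling-like cells and 32.1% of cluster 13. They also made up 15 of the 20 WT liver cells of clusters 2, 10 and 12 (75.0%, 50.9 to 91.3), 12 of them from 1 clone.

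Liver clones were shared with the spleen of the same mice. In WT, 63 clones were found in both organs, 3.13% (2.42 to 3.99) of liver clones and 12.4% (11.1 to 13.8) of liver cells. In EomesTG, 28 were found in both, 2.73% (1.82 to 3.93) of liver clones and 12.5% (11.4 to 13.7) of liver cells. No clone was shared between libraries of different genotypes, where a count of 0 allows up to 0.0774% of WT spleen clones and 0.293% of EomesTG liver clones. Of the liver clones of at least 3 cells, 19 of 43 were seen in spleen in WT, 44.2% (29.1 to 60.1), and 12 of 81 in EomesTG, 14.8% (7.90 to 24.4). How many clones are seen in both organs depends on the number of cells read from each.

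EomesTG clones used TRA gene segments near the middle of the TRA locus more than WT clones in both organs. TRAV genes lie on chromosome 14 from TRAV1 (start 52427928) to TRAV21-DV12 (start 53875984), followed by TRAJ genes from TRAJ58 (start 54157280) to TRAJ2 (start 54217836). The 44 of 89 TRAV genes farthest from the TRAJ genes were used by 25.1% (23.8 to 26.5) of EomesTG and 39.7% (38.2 to 41.3) of WT spleen clones, and by 22.5% (19.9 to 25.1) and 39.3% (37.2 to 41.5) of liver clones. The 21 of 43 TRAJ genes nearest to the TRAV genes were used by 64.2% (62.7 to 65.6) and 41.7% (40.2 to 43.3) of spleen clones, and by 68.2% (65.2 to 71.0) and 43.7% (41.5 to 45.9) of liver clones. These measures were chosen after the use of single V genes had been seen. The largest differences of single TRAV genes in spleen were lower TRAV3D-3 (1.94% against 4.33%), TRAV9D-3 (1.86% against 3.61%) and TRAV16N (2.33% against 3.64%) and higher TRAV6-7-DV9 (3.61% against 1.73%), TRAV16 (3.90% against 2.14%) and TRAV5-4 (3.56% against 1.83%) in EomesTG. In liver they were lower TRAV9D-3 (1.66% against 4.08%) and higher TRAV6-7-DV9 (4.20% against 1.34%), TRAV5-4 (4.10% against 1.94%) and TRAV4-4-DV10 (3.03% against 1.04%), and intervals overlapped for TRAV16N and TRAV3D-3. Assignments among near-identical D and N copies of TRAV genes are uncertain.

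**Figure D4:**
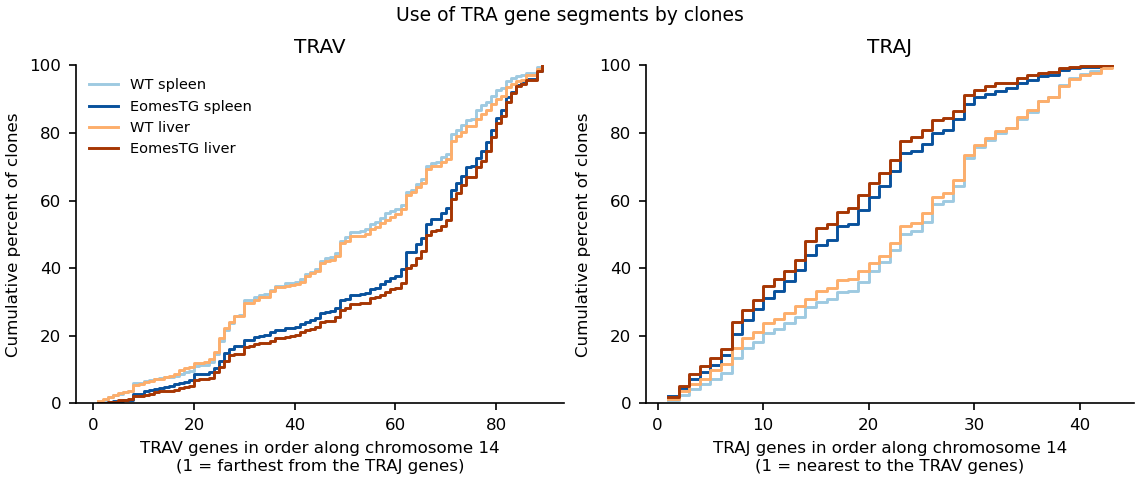
Cumulative percent of clones along the 89 TRAV genes (left, from the gene farthest from the TRAJ genes) and the 43 TRAJ genes (right, from the gene nearest to the TRAV genes) on chromosome 14, 1 line per library. The EomesTG lines lie below the WT lines on the left, at 25.1% against 39.7% of spleen clones after 44 genes, and above them on the right.

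In spleen, EomesTG clones used less TRBV14 (3.29% against 4.77%) and TRBV26 (1.57% against 2.55%) and more TRBV13-3 (7.16% against 5.60%) and TRBV31 (3.41% against 2.32%) than WT clones. In liver they used less TRBV10 (1.86% against 3.88%). Liver against spleen, WT clones used less TRBV13-1 (5.17% against 7.40%) and more TRBV12-2 (10.1% against 7.69%), and EomesTG clones used less TRBV10 (1.86% against 3.48%). For the other TRBV genes that the rule names, and for all TRAV genes that it names between organs, the intervals of the 2 shares overlapped. The TRAV11-TRAJ18 chain of invariant NKT cells was found in 18, 2, 11 and 6 cells of WT spleen, EomesTG spleen, WT liver and EomesTG liver (0.452%, 0.0481%, 0.462% and 0.184%). Of clones, these were 0.464%, 0.0491%, 0.547% and 0.586%, and in liver the intervals, 0.274 to 0.977 in WT and 0.215 to 1.27 in EomesTG, overlapped. The TRAV1-TRAJ33 chain of MAIT cells was found in 3, 0, 7 and 0 cells, where 0 allows up to 0.0722% in EomesTG spleen and 0.0923% in EomesTG liver.

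In WT liver, cells of expanded clones (at least 3 cells) had more RNA of effector and cell cycle genes than cells of single-cell clones. Against 1927 single-cell clones, the 374 expanded cells had more of the effector receptor genes Klrg1 (3.43, 95% interval 3.16 to 3.71) and Cx3cr1 (3.24, 2.96 to 3.53), the galectin gene Lgals3 (3.26, 3.06 to 3.46), the metallothionein gene Mt3 (3.72, 3.02 to 4.45) and Stk32c (3.40, 2.84 to 3.98). They had less of the lymph node homing gene Ccr7 (−4.48, −4.99 to −4.02), and of Dapl1 (−4.38, −5.19 to −3.68), Igfbp4 (−5.51, −8.56 to −3.65) and Nsg2 (−4.00, −4.66 to −3.41). Pdcd1 (1.996, 1.68 to 2.31) and Cxcr6 (1.06, 0.92 to 1.20) were higher, and Eomes was at 0.22 (0.015 to 0.43), or −0.091 with each clone counted once. All 14 cell cycle genes (median 1.82) and 10 of 12 cytotoxic effector genes (median 2.31) were higher, as were 11 of 13 inhibitory receptor genes (median 1.08), and 11 of 12 naive genes were lower (median −2.18). Immediate early genes were lower in 4 of 14 (median −0.33, or 0.040 with each clone counted once), with Fos −1.65 and Fosb −1.55, and heat shock genes in 4 of 10 (median −0.40). The median over all genes was 0.24. The 2 sides differed in cell class: of cells with both chains, 0 of 102 naive-like and 2 of 957 immediate-early-like cells were expanded. The ratios were not taken within classes, so they also hold that difference. The largest clone gave 114 of the 374 expanded cells.

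In EomesTG liver, cells of expanded clones had more RNA of inhibitory receptor and cell cycle genes than cells of single-cell clones. The 2250 expanded cells had more Prss2 (6.60, 95% interval 5.38 to 8.23), C2cd4b (7.49, 5.0001 to 12.80), Ociad2 (5.93, 4.37 to 8.22), Coch (6.17, 4.31 to 9.23) and Lim2 (4.95, 4.26 to 5.73) than the 884 cells of single-cell clones. C2cd4b rests on 1 UMI, Coch on 2 and Ociad2 on 3 in the latter. They had less Ccr7 (−7.36, −8.07 to −6.72), Satb1 (−6.03, −6.64 to −5.48), St6gal1 (−7.90, −13.22 to −5.40) and Tmem108 (−6.71, −8.60 to −5.33). Pdcd1 (3.52, 3.36 to 3.69), Cxcr6 (2.51, 2.37 to 2.65) and Eomes (0.72, 0.59 to 0.85) were higher. Inhibitory receptor and exhaustion genes were higher in 12 of 13 (median 2.95), with Cd200r1 3.56, Havcr2 3.29 and Entpd1 3.14. Cell cycle genes were higher in all 14 (median 1.43). Naive genes were lower in 11 of 12 (median −5.50) and egress genes in 9 of 10 (median −2.73). Cytotoxic effector genes were higher in 7 and lower in 2 of 12 (median 0.97; Gzma 3.51 and Gzmm −3.95). The median over all genes was 0.34, and the difference between the genotypes in these within-library ratios was not tested. The 2 sides differed in cell class here too: clusters 2, 10 and 12 held 2035 of the 2250 expanded cells. Of naive-like cells with both chains 0 of 144 were expanded, and of immediate-early-like cells 1 of 346. The ratios were not taken within classes, so they also hold that difference. The 2 largest clones gave 492 and 447 of the expanded cells. The spleen libraries, with 82 and 48 expanded cells in WT and EomesTG, were not compared.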

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

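Of the tests in this part, those of the makeup of the spleen libraries, of the makeup of their naive-like class and of free Cxcr6 RNA were chosen only after the result was seen, and the alternative without clusters 2, 10 and 12 was added after the clusters were seen. The test of Fyco1 was set before its value was seen, was taken out in favour of that of free RNA after it was seen, and is given here again. Among the genes named by the rule, for 8 the ratio of EomesTG to WT lay on opposite sides of equality in the 2 organs, past 1.5-fold with intervals to match, which is what singled them out; the difference between organs was not tested, as each value rests on 1 library. Of these, 7 were lower in EomesTG spleen and higher in EomesTG liver: Gzma (−1.60 in spleen, 3.07 in liver, difference 4.67), Chn2 (−2.36 in spleen, 2.11 in liver, difference 4.47), Cxcr6 (−2.42 in spleen, 1.30 in liver, difference 3.72), Klre1 (−1.33 in spleen, 1.82 in liver, difference 3.15), Fasl (−1.16 in spleen, 1.19 in liver, difference 2.35), Ccl5 (−0.64 in spleen, 1.53 in liver, difference 2.16) and Cd160 (−1.19 in spleen, 0.62 in liver, difference 1.81), all log2. Without clusters 2, 10 and 12 the liver ratio of Ccl5 was −0.098, that of Cxcr6 −0.29 and that of Cd160 −0.14 (−0.23 to −0.059), on the side of spleen, and those of Klre1, Chn2 and Fasl were 0.22, 0.29 and 0.016, short of 1.5-fold. Those of Gzma and Fosb were 1.18 and −0.72. The immediate early gene Fosb (1.91 in spleen, −1.11 in liver, difference −3.02) went the other way. Cells of other types, outside every comparison, made up 0.730% of WT liver and 0.0885% of EomesTG liver barcodes, and are listed because no comparison covers them.

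For Cxcr6, the liver ratio without clusters 2, 10 and 12 was −0.29 (−0.39 to −0.19), below 0 as in spleen. That outcome was predicted before the value was seen, but a fall of the ratio was built into the test. These clusters came mostly from EomesTG liver and stood at 579, 472 and 533 Cxcr6 CPM, against 145 over WT liver. Leaving them out cannot tell a different makeup of the liver libraries from a changed state of the same cells. Makeup does not account for spleen, since the ratio was −2.94 within naive-like spleen cells and at most −2.30 (−2.95 to −1.61) in each of their 4 clusters, past the bound of −0.58 set for it. Free Cxcr6 RNA in the WT spleen suspension is argued against: naive-like cells reached 68.3% of the WT spleen level of Cxcr6 but a median of 8.75% over 12 cytotoxic effector genes, a ratio of 0.128, although Prf1 (85.4%), Ctsw (85.3%) and Serpinb9 (71.1%) were as high. Reads of the overlapping gene Fyco1 are argued against by its spleen ratio of −0.16 (−0.30 to −0.009), above the bound of −1 set for it. A lower Cxcr6 level within EomesTG naive-like cells, from the transgene or from a strain variant near the gene, stays open and was not tested.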

How the results depend on the processing

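The alternatives without 2-TRB barcodes, without the NK-like cluster 14, without the immediate-early-like cluster 4, without clusters 2, 10 and 12 and without the 2 largest clones were chosen only after the data were seen; the other 23 settings were planned. Over 1310 results and 6459 alternatives, 4873 stayed within the interval set for the reported value (counts: within 1.5 times), 1559 moved further and 27 reversed. For a list median that interval ran between the medians of its members' own interval bounds. Such bounds describe single genes and not the counting error of a median. Of 262 alternatives of 31 leading results, 58 moved and 0 reversed. Cxcr6 in liver is not among these; it ranged from −0.29 to 1.55 and reversed without clusters 2, 10 and 12. Over their alternatives, the ratio of Eomes ranged from 0.61 to 0.74 in spleen and from 0.62 to 1.30 in liver, that of Pdcd1 in liver from 2.64 to 4.38 and that of Cxcr6 in spleen from −2.57 to −2.34. Depth and counting error limit genes with few UMIs, and no alternative covers the spread between mice, since each group has 1 library. No paired analysis was possible because the mice were pooled. Values follow with the reported value in parentheses, in log2 unless a percent; the cause was not tested.

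With genes of at least 200 UMIs: liver genotype, transcription factors median 0.0052 (−0.18). In paired cells: EomesTG tissue, inhibitory receptors median 3.77 (3.89), and for liver genotype, naive median −1.26 (−1.16). With the deposited clonotype identifier: thinned share in clones of at least 3 cells, EomesTG liver 64.0% (68.0%), WT liver 14.1% (15.7%). With doublets kept: naive-like share, WT spleen 52.5% (55.5%). In expanded against single-cell clones, each counted once: expanded clones, WT liver, Cd6 0.043 (−0.65), Dnajb1 0.096 (−0.84), Eomes −0.091 (0.22), immediate early median 0.040 (−0.33), and for expanded clones, EomesTG liver, chemokine receptors and integrins median 0.19 (−0.32). With each clone counting once: liver minus spleen genotype ratio, Cxcr6 2.49 (3.72), Eomes 0.028 (0.48), Pdcd1 1.94 (3.68), and for liver genotype, Eomes 0.74 (1.10), Il2ra 0.10 (−1.22), glycolysis median −0.067 (0.11), inhibitory receptors median 1.24 (2.47), memory median 0.055 (−0.33), naive median −0.21 (−1.16), transcription factors median 0.035 (−0.18), and for spleen genotype, Eomes 0.71 (0.63), cytotoxic effector median −0.50 (−1.04), and for WT tissue, immediate early median 2.64 (2.51), and for EomesTG tissue, inhibitory receptors median 2.78 (3.89), residency median 4.10 (4.86). With the mean of each cell's CPM: liver genotype, Eomes 1.30 (1.10), inhibitory receptors median 2.18 (2.47), naive median −1.48 (−1.16), and for spleen genotype, Eomes 0.74 (0.63), and for WT tissue, immediate early median 2.64 (2.51), and for EomesTG tissue, inhibitory receptors median 4.01 (3.89). With median-of-ratios scaling: liver genotype, Eomes 0.99 (1.10), glycolysis median −0.0033 (0.11), naive median −1.28 (−1.16), and for WT tissue, egress median −0.012 (0.065), and for EomesTG tissue, inhibitory receptors median 3.69 (3.89), mitochondrial oxidation median −0.042 (0.16). Within classes, each clone counted once: other T cells, liver genotype, chemokine receptors and integrins median 0.11 (−0.44), glycolysis median −0.047 (0.12), memory median 0.12 (−0.34), transcription factors median 0.10 (−0.16), and for other T cells, spleen genotype, cytotoxic effector median 0.060 (−0.37). At clustering resolution 0.5: naive-like share, EomesTG liver 5.80% (4.50%), EomesTG spleen 85.8% (73.3%), WT liver 6.24% (4.45%), WT spleen 74.9% (55.5%). With variable genes chosen per library: naive-like share, EomesTG spleen 71.6% (73.3%), WT liver 5.31% (4.45%). Without the largest clone: thinned share in clones of at least 3 cells, EomesTG liver 62.8% (68.0%), WT liver 11.5% (15.7%), WT spleen 0.559% (1.58%).

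Without clusters 2, 10 and 12: liver minus spleen genotype ratio, Cxcr6 2.23 (3.72), Eomes 0.0036 (0.48), Pdcd1 2.36 (3.68), and for liver genotype, Ccl5 −0.098 (1.53), Cxcr6 −0.29 (1.30), Eomes 0.62 (1.10), cytotoxic effector median −0.18 (0.12), inhibitory receptors median 0.89 (2.47), naive median −0.093 (−1.16), residency median −0.14 (0.45), lower naive genes 1 (9), and for EomesTG tissue, Eomes −0.040 (0.44), inhibitory receptors median 3.02 (3.89), interferon response median 0.044 (−0.20), residency median 3.93 (4.86). Without the 2 largest clones: thinned share in clones of at least 3 cells, EomesTG liver 56.5% (68.0%), EomesTG spleen 0.454% (0.899%), WT liver 9.68% (15.7%), WT spleen 0.426% (1.58%). Without the NK-like cluster 14: liver genotype, inhibitory receptors median 2.90 (2.47), naive median −1.25 (−1.16), and for WT tissue, residency median 1.64 (2.35). Without the immediate-early-like cluster 4: liver minus spleen genotype ratio, Cxcr6 3.42 (3.72), Pdcd1 3.23 (3.68), and for liver genotype, Eomes 1.21 (1.10), cytotoxic effector median −0.041 (0.12), glycolysis median −0.021 (0.11), inhibitory receptors median 2.14 (2.47), naive median −1.37 (−1.16), and for WT tissue, egress median −0.012 (0.065), immediate early median 2.09 (2.51), residency median 2.91 (2.35), and for EomesTG tissue, inhibitory receptors median 4.10 (3.89).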

Other observations

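In this part, the tests of a TRA haplotype, of the makeup of the spleen libraries, of free receptor RNA and of barcodes with 2 cells were chosen only after the result was seen. That of the makeup of the naive-like class was added later, with its prediction written before its own value was seen. Within the immediate-early-like cluster 4 of liver, 513 EomesTG and 1195 WT cells, EomesTG cells had less RNA of NK receptor and adaptor genes, 8 of 12 lower (median −1.62), with Fcer1g −4.98, Klrc2 −2.90, Klra7 −2.65 and Klra1 −1.94. Heat shock genes were higher in 6 of 10 (median 0.64), with Hspa1a 1.21 and Hspa1b 1.12. The inflammatory caspase gene Casp1 (2.88, 2.01 to 3.84), Ly6a (2.18, 1.93 to 2.42) and Iigp1 (2.69, 1.82 to 3.62) were higher, and Ppic (−3.1997, −4.43 to −2.19), Anxa2 (−2.10, −2.53 to −1.69) and Cxcr6 (−1.96, −2.52 to −1.45) were lower. Inhibitory receptor genes had 0 of 8 higher in these cells.

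The large clones of EomesTG liver were weighed against technical sources. Of 490 naive-like and immediate-early-like cells of that library with both chains, 1 carried a receptor of a clone of at least 3 cells, 0.204% (0.0052 to 1.13). This argues only against free receptor RNA strong enough to outweigh a cell's own receptor. Each cell kept the chains with the most UMIs, so weaker free RNA could not show and stays open. Barcodes holding 2 cells stay open: without barcodes with 2 productive TRB chains the unthinned share in such clones was 69.6%, but 154 of 3252 barcodes were left out, and had all of them belonged to clones that stayed at 3 cells or more it would have been 67.7%, within the interval of 67.6 to 70.8. No biological explanation was tested, and no clone was assigned to a mouse, so a chance event in 1 of the pooled mice stays open as well.

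The lower use of distal TRAV genes in EomesTG was weighed in the same way. Fewer rounds of TRA rearrangement may explain it, since TRAV genes far from the TRAJ genes and TRAJ genes far from the TRAV genes are joined in later rounds. That predicted, before TRAJ values but after TRAV use were seen, more use of the near TRAJ genes. EomesTG clones exceeded WT by 22.4 percentage points in spleen and 24.5 in liver. Far TRAV and far TRAJ genes are both joined late, so this cannot tell fewer rounds from another cause acting along the whole locus. A haplotype lacking only the D and N copies is argued against, since TRAV genes before the duplicated stretch were used 0.296 times as often as in WT. Makeup of the spleen libraries is argued against by a difference of −15.5 points among naive-like clones, and of −14.9 (−18.1 to −11.8) with their 4 clusters held apart; a strain or haplotype difference over the whole locus was not tested and stays open.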
